A study of Homo sapiens with 36 samples.

How the data were processed

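RNA was measured on 36 Affymetrix human arrays in 12 groups of 3 arrays, taken from subcutaneous xenografts of 4 colorectal cancer models named CR2506, CR3150, CR2513 and CR1560. Per the labels' protocols, treatment began at a tumour volume of 200 mm3, the antibody against RSPO3 was given weekly at 25 mg/kg and irinotecan weekly at 10 mg/kg. Per the labels' protocols, 100 ng of total RNA from each tumour was amplified with the NuGEN Ovation kit before labelling. The tumours held mouse stroma beside the human cancer cells, so transcripts of the host can reach human probe sets. The labels call the arrays of a group biological replicates and do not number the animals, so each p-value measures the spread between arrays alone.

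The deposited values are log2 intensities made by the authors with GCRMA, which corrects background by probe sequence, normalizes arrays by quantiles and summarizes probes, per the submitters' processing notes. No version was given. The lowest value was 1 number within a model and differed between models (2.20 in CR2506, 2.24 in CR3150 and CR2513, 2.16 in CR1560 on the log2 scale), so not all 4 models were normalized together, and levels were compared only within a model. Between 38.2% and 40.6% of the 54675 probe sets of an array lay at that floor. Arrays give no count of molecules; the number of arrays limits the precision.

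Probe sets were named from the reference table of gene names. Of the 54675 probe sets, 42898 had an entry, 41097 had exactly 1 gene symbol, 1801 had several and were left out, and 11777 had no entry. A probe set was kept where its log2 value was at least 4 on at least 3 of the 36 arrays, which held for 26967 probe sets and for 22440 of those with 1 symbol. For each gene the kept probe set with the highest mean over all arrays was used, giving 12087 genes. Values were neither normalized again nor shifted.

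A linear model with 1 mean for each of the 12 groups was fitted to all 36 arrays with limma 3.58.1 in R 4.3.3, with eBayes and an intensity trend. It has 24 residual degrees of freedom and 3.69 prior degrees of freedom. Adjusted p-values are limma's moderated tests with Benjamini-Hochberg adjustment over the 12087 genes within a comparison, with a threshold of 0.05, and "rose", "fell" and "changed" are used only of genes past it. All comparisons are treated minus reference within a model: anti-RSPO3 minus control in 4 models, and irinotecan minus control, combination minus irinotecan, combination minus control and the interaction of antibody and irinotecan in 2 models. The mean of the 4 antibody effects was also tested, and a moderated F test asked whether those effects differ between models. Errors beside log2 differences are standard errors (SE) of that fit with n = 3 arrays per group. The fit holds 1 spread per gene over all 12 groups. Where a gene lies near the floor in some models, their nearly constant arrays lower that spread. Its SE and p-value can then be too small in the models where it is detected. Where the mean of the lower group lay below the limit of 4, each of its arrays below 4 was set to 4 for the fold, which is given as "at least". No fold is given where the means of both groups lay below it. This rule was widened after seeing the data from groups with all 3 arrays below 4.

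The 21 gene lists were written from textbook knowledge before the data were examined, as were the comparisons, the rule for naming genes and the first set of alternatives. The lists are R-spondin and LGR axis, Wnt targets and feedback, intestinal stem cell, absorptive colonocyte, goblet and mucin, enteroendocrine, Paneth and crypt base secretory, S phase, G2 and M phase, p53 targets, hypoxia and glycolysis, interferon response, YAP and regenerative, irinotecan handling, colorectal epithelium, fibroblast and matrix, endothelium, myeloid, human B cell, keratinised squamous epithelium, and skeletal muscle and fat. They hold 315 different genes, of which 231 were tested, 68 were too dim and 16 had no probe set with 1 symbol. Each list was tested against the other genes with limma's camera at a preset correlation of 0.01, adjusted over the 21 lists within a comparison, and again with an estimated correlation. Named genes are any tested members of the R-spondin, Wnt and stem cell lists, the 5 largest rises and 5 largest falls of a comparison among changed genes whose arrays did not overlap between the groups (chance gives 10% of genes such a separation at 3 against 3), and up to 4 members of each other list with the largest absolute difference. Genes named outside that rule are said to be chosen after their values were seen.

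Overlaps of calls were tested with Fisher's exact test, 2-sided, over the genes detected in both models of a pair, for pairs of comparisons that share no array. RNA quality was measured as the log2 difference between 3 prime and 5 prime control probe sets of GAPDH and ACTB, compared between groups with an exact 2-sided permutation test, whose smallest possible p at 3 against 3 is 0.1. Adjusted over the 20 such tests, the smallest p was 0.143.

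The scripts were tested on simulated data. With equal spread on all arrays and 226 of 12087 genes changed in a simulated CR2506 comparison, 9 of 188 calls were false (4.79%). There 75% of 100 genes changed 2-fold and 96.0% of 99 genes changed 4-fold were recovered, the shifted list was called and 0 other lists were. With the spread of each array and model as measured, 200 genes changed in a simulated CR2506 comparison gave 34 false calls among 218, and in CR3150 199 among 384, while fits of those models alone gave 2 among 162 and 2 among 149. In CR2513 37 of 215 calls were false, against 5 of 184 in the fit of that model alone. In the same simulations 84% and 90% of genes changed 2-fold were recovered in CR2506 and CR3150. In 20 simulations with no effect, the mean number of false calls was 100.8 for the antibody in CR3150, 8.95 in CR2513, 6.9 in CR1560 and 2.9 in CR2506, and it was 159.1 for combination minus irinotecan in CR2506.

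Alternatives fixed in advance were no filter or a stricter filter on dim probe sets (log2 of at least 6), the mean of all probe sets of a gene, quantile normalization once more across all arrays, a fit of each model alone, no intensity trend, array weights, the replicate number as a block, and each array left out in turn. Added after the data were seen were a fit of each model alone over the genes detected in it, the GAPDH difference as a covariate, the CR2506 combination group without arrays 2 and 3, the mean of the 2 models with equal treatment durations, the test of differing effects on genes detected in all 4 models, values below 4 set to 4, and overlaps of genes ranked in fits of each model alone or called with the covariate. Whether same-numbered arrays deviate together was checked by the correlation of their deviations from the group means. Each of the 3 such pairs exceeded 0.1 for the CR1560 control and anti-RSPO3 arrays (0.633, 0.161 and 0.456) and for the CR1560 anti-RSPO3 and combination arrays (0.172, 0.111 and 0.432). The numbers may pair those arrays, which was considered after the fits had been seen. Between the CR1560 control and combination arrays the correlations were 0.169, -0.125 and 0.224, so such a pairing is not settled. That pairing comes from these correlations and not from the labels. No array was left out of the reported values.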

Results

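Human transcripts were measured in whole tumours of 4 patient-derived xenograft models of colorectal cancer carried in immunodeficient mice, 36 arrays in 12 groups of 3. Every model had a group given a control antibody and a group given an antibody against RSPO3, a secreted protein that binds LGR receptors and raises Wnt signalling. CR2506 and CR1560 also had a group given irinotecan, a topoisomerase I inhibitor used against colorectal cancer, and a group given both agents. The labels give unequal treatment durations. In CR2506 they are 4 weeks for the controls and 7 weeks for the other groups, and in CR3150 3 and 7 weeks. In CR2513 all groups have 7 weeks and in CR1560 6 weeks, while the series text gives 4 weeks for all. The comparisons ask what the antibody does to each tumour, alone and on top of irinotecan. Values are log2 intensities after the authors' GCRMA normalization, and 10915, 10837, 10532 and 10987 of the 12087 tested genes (1 probe set each) were detected in CR2506, CR3150, CR2513 and CR1560.

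In CR2506 the antibody, at 7 weeks against 4 for the controls, went with lower Wnt target transcripts and higher transcripts of mature colon cells. LGR5, the receptor that marks intestinal stem cells, fell at least 11.4-fold (log2 difference -4.98 ± 0.71 SE, n = 3 per group, adjusted p = 2.32e-05). SLC26A3, the chloride exchanger of surface colonocytes, rose at least 65.8-fold (7.84 ± 0.49, adjusted p = 7.93e-12) from the array floor, and CA1, a colonocyte carbonic anhydrase, rose at least 53.5-fold (6.31 ± 0.77). Of 27 tested genes of the absorptive colonocyte list 22 rose and 1 fell, with the same counts adjusted over the list alone, and the list was shifted up (camera adjusted p = 6.89e-25; adjusted p = 4.5e-05 with an estimated correlation). CLCA4 rose at least 26.9-fold and LYPD8 at least 26.4-fold. In the goblet and mucin list 11 of 22 members rose (12 adjusted over the list alone; adjusted p = 0.0023 with an estimated correlation), among them the mucins MUC5B (at least 8.68-fold), MUC12 (13.4-fold) and MUC2 (3.61-fold). The call of MUC2 ended without control replicate 1 (log2 difference 1.58) or 3 (1.74) and without anti-RSPO3 replicate 2 (1.86) or 3 (1.40).

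Among 13 tested Wnt targets and feedback genes of CR2506, 6 fell and 1 rose (7 and 2 adjusted over the list alone; adjusted p = 0.00262, and adjusted p = 0.042 with an estimated correlation). The falls were LGR5, ASCL2 (at least 1.94-fold), a transcription factor of stem cells, AXIN2 (3.98-fold) and ZNRF3 (3.68-fold), feedback inhibitors of the pathway, BMP4 (3.43-fold) and the cyclin CCND1 (1.55-fold). The secreted Wnt inhibitor DKK4 rose at least 3.96-fold. In the intestinal stem cell list 6 of 13 fell, including RGMB (2.64-fold), EPHB3 (at least 1.36-fold) and CDCA7 (4.74-fold), and OLFM4 rose 2.15-fold; this list's shift had an adjusted p of 0.0299, and adjusted p = 0.25 with an estimated correlation. RSPO3 itself had a log2 difference of 0.26 ± 0.15 (adjusted p = 0.247). In the S phase list 7 of 20 members fell (15 adjusted over the list alone), with GINS2 3.85-fold and CDC6 3.25-fold lower, and adjusted p = 0.325 with an estimated correlation. PLK1, a mitotic kinase, fell 3.31-fold, and 2 of 20 genes of the G2 and M phase list fell (2 adjusted over the list alone; adjusted p = 0.504 with an estimated correlation). In the hypoxia and glycolysis list 4 of 15 fell (5 adjusted over the list alone; adjusted p = 0.325 with an estimated correlation), with the glucose transporter SLC2A1 3.27-fold lower. The S phase count was 3 without control replicate 3 and 4 without anti-RSPO3 replicate 1, the hypoxia count 7 without anti-RSPO3 replicate 3, and the G2 and M phase count 1 without any 1 of the 6 arrays. Of 31 named genes past the test in this model, 21 stayed past it with each array left out in turn. Without control replicate 3 the calls of CDCA7 (-2.03), DKK4 (1.89), OLFM4 (0.77) and CDC6 (-1.34) ended. Without anti-RSPO3 replicate 2 those of AXIN2 (-1.35) and CDC6 (-1.42) ended. That of EPHB3 ended without control replicate 1 (-0.55), 2 (-0.50) or 3 (-0.55) or anti-RSPO3 replicate 1 (-0.41).

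Genes that handle irinotecan also moved in CR2506. ABCB1, a drug efflux pump, rose at least 46.2-fold (log2 difference 7.20 ± 0.22, adjusted p = 1.15e-19), ABCG2, another pump, rose 8.08-fold, and CES2, an esterase that activates irinotecan, rose 1.79-fold. That list had 5 of 7 members higher (6 adjusted over the list alone; adjusted p = 4.5e-05 with an estimated correlation). PADI2, an arginine deiminase, rose at least 49.7-fold, and FOLR1, a folate receptor, fell at least 9.003-fold. Of 21 p53 targets CDKN1A rose (1.91-fold) and 1 fell (1 rise and 0 falls adjusted over the list alone); the fall was of CCNG1, named after its value was seen (-0.55, adjusted p = 0.0452), and ended without any 1 of the 6 arrays (-0.50 to -0.61). Muscle-type transcripts in the fibroblast and matrix list, TAGLN (3.06-fold) and MYL9 (-1.26 ± 0.34), fell, 2 of 9 members (2 adjusted over the list alone). Both calls ended without control replicate 1 (-1.65 and -1.08), and that of TAGLN without control replicate 2 (-1.65) or 3 (-1.53) or anti-RSPO3 replicate 1 (-1.28), which left 1 member. In all, 1854 of 12087 genes changed, 835 up and 1019 down. The arrays of the treated group had a larger GAPDH 3 prime minus 5 prime difference (0.508 ± 0.173 SD against 0.273 ± 0.0268 SD, n = 3, exact permutation p = 0.1). The count was 1207, 1188 and 1152 without control replicates 1, 2 and 3. It was 682 (437 up and 245 down) in a fit of this model alone over the genes detected in it, as in all such fits named for other comparisons. With the GAPDH difference as a covariate it was 926 (533 up and 393 down), so rises outnumbered falls in both, and both were chosen after seeing the data.

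**Figure D1:**
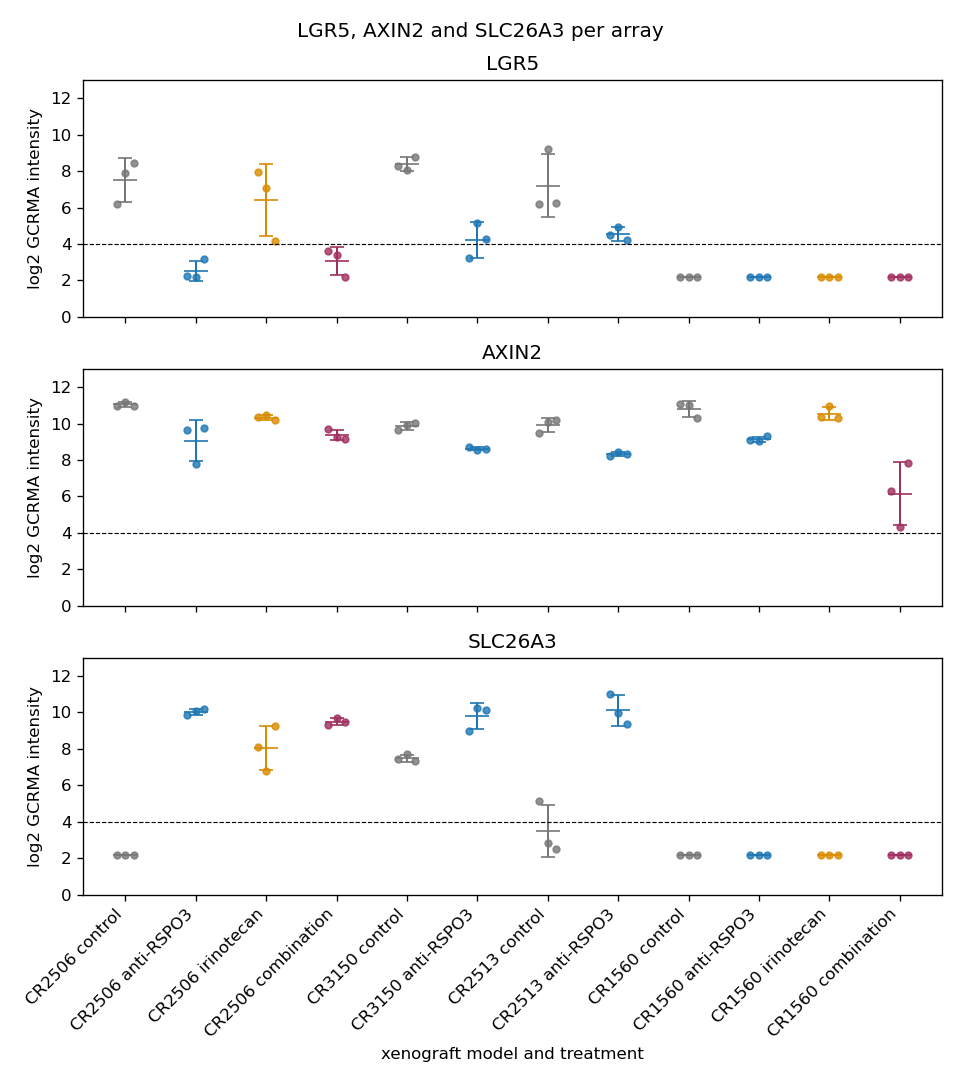
Log2 GCRMA intensity of LGR5, AXIN2 and SLC26A3 (vertical axes) for the 12 groups (horizontal axis); points are single arrays, the horizontal marks are means and the bars 1 SD (n = 3), and the dashed line is the detection limit of 4. LGR5 lay below the control arrays on all anti-RSPO3 arrays of CR2506, CR3150 and CR2513 and at the floor of 2.16 on all arrays of CR1560, where AXIN2 was lowest in the combination group.

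CR3150, at 7 weeks with the antibody against 3 for the controls, had lower LGR5 and Paneth cell transcripts, and antibody and duration cannot be told apart there. LGR5 fell 17.9-fold (log2 difference -4.16 ± 0.71 SE, n = 3 per group, adjusted p = 0.00065), the stem cell gene SMOC2 at least 2.30-fold, RGMB 4.44-fold, ASCL2 4.13-fold, BMP4 2.36-fold and EPHB3 1.83-fold. The intestinal stem cell list had 5 of 13 members lower (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.00255, and adjusted p = 0.117 with an estimated correlation), and the Wnt targets and feedback list 3 of 13 (6 adjusted over the list alone; adjusted p = 0.0204, and adjusted p = 0.117 with an estimated correlation). REG1A, a secreted lectin of the crypt base, fell at least 126-fold (-8.09 ± 1.55, adjusted p = 0.00177), the defensin DEFA6 at least 5.03-fold and the antibacterial lectin REG3A at least 6.87-fold, so 3 of 6 Paneth and crypt base secretory genes fell (3 adjusted over the list alone; adjusted p = 0.0021 with an estimated correlation). Of 27 absorptive colonocyte genes 6 rose (8 adjusted over the list alone; adjusted p = 5.67e-06, and adjusted p = 0.0457 with an estimated correlation), among them SI, the brush border sucrase-isomaltase (7.93-fold), CLCA4 (5.67-fold) and SLC26A3 (4.97-fold). RSPO3 rose (0.68 ± 0.15), and CDX2, an intestinal transcription factor, fell 2.93-fold. Of 21 named genes past the test in this model, 14 stayed past it with each array left out in turn. ASCL2 did not without control replicate 1 (-1.98), 2 (-2.13) or 3 (-2.03) or anti-RSPO3 replicate 2 (-1.52) or 3 (-2.07), nor SMOC2 without control replicate 1 (-2.00) or 3 (-2.04) or anti-RSPO3 replicate 1 (-1.50) or 3 (-1.57). The stem cell count was 3 without control replicate 1 or 3 or anti-RSPO3 replicate 3.

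Transcripts of other cell types moved with the antibody in CR3150. PTPRC (3.31-fold) and AIF1 (at least 3.25-fold), leukocyte and macrophage markers, rose, 2 of 3 tested myeloid genes (2 adjusted over the list alone; adjusted p = 0.0457 with an estimated correlation), as did the matrix genes COL3A1 (1.71-fold) and VIM (1.62-fold). The immunoglobulin probe sets named IGHG1 and Igk rose at least 70.05-fold and 36.6-fold, the latter under a symbol written in the style of a mouse gene. Whether either probe set reads human or mouse transcripts is not given in the sources used here. IGHG1 also varied among controls, from 8.33 to 13.64 log2 in CR1560 and from 2.52 to 7.33 in CR2506. Their calls ended without any 1 of the 3 controls or without anti-RSPO3 replicate 1 or 3 (6.22 to 7.78 for IGHG1 and 4.58 to 5.32 for Igk). The same 5 omissions ended the call of VIM (0.52 to 0.79), control replicate 3 or anti-RSPO3 replicate 3 that of COL3A1 (0.56 and 0.61), and control replicate 3 or anti-RSPO3 replicate 1 that of AIF1 (1.68 and 1.18), which left 1 myeloid gene. Of 17 interferon response genes 2 fell (5 adjusted over the list alone), HERC5 by at least 1.85-fold (5 fell without anti-RSPO3 replicate 1), and the list's shift had adjusted p = 0.465 with an estimated correlation. CXCL10, an interferon-induced chemokine, had a log2 difference of -2.36 ± 0.98 (adjusted p = 0.143).

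In total 839 genes changed in CR3150, 294 up and 545 down (35.04% rises; 50.2% of 747 calls rose after quantile normalization once more). The treated arrays had a GAPDH 3 prime minus 5 prime difference of 0.685 ± 0.0128 SD against 0.415 ± 0.0653 SD (n = 3, exact permutation p = 0.1). A fit of this model alone over the genes detected in it, chosen after seeing the data, called 1 gene, REG1A (adjusted p = 0.00362), with 1834 genes at an unadjusted p under 0.05. Counts were 443, 474 and 348 without control replicates 1, 2 and 3, 538 without anti-RSPO3 replicate 3 and 1640 without anti-RSPO3 replicate 2, and 260 with the GAPDH difference as a covariate.

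CR2513, with equal durations of 7 weeks, gained colonocyte transcripts under the antibody. SLC26A3 rose at least 52.9-fold (log2 difference 6.61 ± 0.49 SE, n = 3 per group, adjusted p = 7.95e-10), CA1 35.7-fold (5.16 ± 0.77, adjusted p = 0.000253), the adhesion molecule CEACAM7 15.5-fold and the carbonic anhydrase CA2 2.81-fold. The absorptive colonocyte list had 7 of 27 members higher (13 adjusted over the list alone; adjusted p = 8.19e-09, and adjusted p = 0.0284 with an estimated correlation). CLDN8, a tight junction protein, rose 19.6-fold and CWH43 at least 7.47-fold. LGR5 fell 6.34-fold (-2.66 ± 0.71, adjusted p = 0.0281) and RGMB 1.97-fold; AXIN2 had a log2 difference of -1.61 ± 0.49 (adjusted p = 0.0567) and ASCL2 of -1.46 ± 0.58 (adjusted p = 0.153). Of 13 stem cell genes 2 fell (2 adjusted over the list alone; adjusted p = 0.228 with an estimated correlation), and of 13 Wnt targets and feedback genes 1 fell (2 lower and 1 higher adjusted over the list alone; adjusted p = 0.0857). Of 15 named genes past the test in this model, 3 (SLC26A3, CA1 and CWH43) stayed past it with each array left out in turn. LGR5 did not without control replicate 2 (-1.67) or anti-RSPO3 replicate 1 (-2.63) or 3 (-2.50), nor RGMB without the same arrays (-0.57, -0.91 and -0.96), which left 0 stem cell genes past the test. CLDN8 did not without control replicate 1 (3.33) or anti-RSPO3 replicate 1 (4.37), CEACAM7 without control replicate 1 (3.97) or 2 (3.49) or anti-RSPO3 replicate 1 (3.43), nor CA2 without control replicate 2 (0.87) or anti-RSPO3 replicate 1 (1.23) or 3 (1.63). The colonocyte count was 4 without control replicate 2 and 2 without anti-RSPO3 replicate 1.

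Interferon and hypoxia genes moved in part in CR2513, and neither list's shift held with an estimated correlation. In the interferon response list 5 of 17 rose (5 adjusted over the list alone; adjusted p = 3.24e-06, and adjusted p = 0.31 with an estimated correlation), including the transcription factor IRF7 (2.56-fold) and OAS3 (2.01-fold), an enzyme that senses viral RNA. Of 15 hypoxia and glycolysis genes 4 fell (9 lower and 1 higher adjusted over the list alone; adjusted p = 0.214 with an estimated correlation), EGLN3, an oxygen sensor (-1.26 ± 0.28), and the enolase ENO2 by 1.71-fold. CCN1 (2.79-fold) and LATS2 (2.14-fold), targets of YAP, rose, 3 of 10 members of the YAP and regenerative list (3 adjusted over the list alone; adjusted p = 0.0931 with an estimated correlation). ESAM, an endothelial adhesion molecule, rose 3.60-fold. Each of these calls ended without anti-RSPO3 replicate 1, where IRF7 had 1.29, OAS3 0.91, EGLN3 -1.07, ENO2 -0.68, CCN1 1.39, LATS2 0.93 and ESAM 1.75. Without anti-RSPO3 replicate 3 the calls of OAS3 (0.97), EGLN3 (-1.16), CCN1 (1.11), LATS2 (1.04) and ESAM (1.65) ended. Without control replicate 1 those of OAS3 (0.97), ENO2 (-0.56), CCN1 (1.52) and ESAM (1.77) ended, without control replicate 2 those of OAS3 (0.87), CCN1 (1.33) and ESAM (1.55), and without control replicate 3 those of ENO2 (-0.70), CCN1 (1.59) and LATS2 (0.77). The interferon count was 3, 2, 1 and 2 without control replicates 1 and 2 and anti-RSPO3 replicates 1 and 3. The hypoxia count was 2 without control replicate 1 or 3, 0 without anti-RSPO3 replicate 1 and 1 without anti-RSPO3 replicate 3, and the YAP count 1 without control replicate 2 and 0 without control replicate 3 or anti-RSPO3 replicate 1 or 3. Altogether 560 genes changed, 390 up and 170 down. A fit of this model alone over the genes detected in it called 1 gene, CWH43 (adjusted p = 0.0161), with 2258 genes at an unadjusted p under 0.05. Counts were 340, 321, 106, 934 and 215 without control replicates 1 and 2 and anti-RSPO3 replicates 1, 2 and 3. With the GAPDH difference as a covariate 52 genes changed, and that difference was 1.16 ± 0.237 SD in treated against 0.712 ± 0.111 SD in control arrays (n = 3, exact permutation p = 0.1).

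In CR1560 few genes passed the test. TNFRSF19, a Wnt target, fell 3.79-fold (log2 difference -1.92 ± 0.26 SE, n = 3 per group, adjusted p = 0.000218), HOPX, a homeodomain protein of reserve stem cells, 3.82-fold, and the class II antigen presentation gene HLA-DPA1 8.86-fold (-3.15 ± 0.47). HLA-DPB1, its partner chain, fell at least 1.77-fold, STRA6, a retinol transporter, at least 1.52-fold, and FAM167A rose 1.70-fold. TNFRSF19 was detected in 1 model, so its SE may be too small beside SDs of 0.704 (anti-RSPO3) and 0.608 (control). AXIN2 had a log2 difference of -1.64 ± 0.49 (adjusted p = 0.473), while LGR5 and SLC26A3 lay at the floor on all arrays of this model. The Wnt targets and feedback list had 1 of 13 members lower (3 adjusted over the list alone) and was shifted down (adjusted p = 1.96e-05; adjusted p = 0.0072 with an estimated correlation). Of 22 goblet and mucin genes 0 rose (2 adjusted over the list alone), and the list was shifted up (adjusted p = 4.16e-05; adjusted p = 0.0484 with an estimated correlation), with REG4 at 1.54 ± 0.46 (adjusted p = 0.482), and at 2.27 without anti-RSPO3 replicate 3, where it passed (adjusted p = 0.015). In all 9 genes changed, 2 up and 7 down, against 410 at an unadjusted p under 0.05; a fit of this model alone called 0 genes in limma, with 905 at an unadjusted p under 0.05. None of the 6 named genes past the test passed in that fit, and HOPX did not without control replicate 2 (-2.04) or 3 (-1.71) or anti-RSPO3 replicate 1 (-1.70) or 2 (-1.77). Counts were 14 and 37 without control replicates 1 and 3 and 19 and 17 without anti-RSPO3 replicates 2 and 3. Simulated data with no effect gave 6.9 calls on average in this comparison. The GAPDH 3 prime minus 5 prime difference was 0.284 ± 0.0180 SD in treated against 0.238 ± 0.0783 SD in control arrays (n = 3, exact permutation p = 0.4). Of the 4 models, only in CR1560 did antibody and control arrays overlap in that GAPDH difference, and this model also had the fewest calls. For ACTB the arrays overlapped in CR1560 and also in CR2513, which had 560 calls. There the ACTB difference was 2.42 ± 0.108 SD in treated against 2.28 ± 0.101 SD in control arrays (n = 3, exact permutation p = 0.2).

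Averaged over the 4 models, LGR5 fell (log2 difference -2.95 ± 0.36 SE, adjusted p = 3.5e-06), as did ASCL2 (-1.79 ± 0.29), AXIN2 (-1.62 ± 0.25), ZNRF3 (-1.18 ± 0.22), RGMB (-1.12 ± 0.13) and BMP4 (-0.90 ± 0.12). SLC26A3 (4.19 ± 0.25), CA1 (3.34 ± 0.38) and ABCB1 (1.85 ± 0.11) rose, and RSPO3 (0.40 ± 0.07) and its receptor LGR4 (0.31 ± 0.08) rose by less. LGR5 and SLC26A3 lie at the floor in CR1560, which adds 0 to their means, and ASCL2 and CA1 were detected in 2 models and ABCB1 in 1. Values below 4 were also set to 4, a setting chosen after seeing the data. The means were then -2.52 ± 0.33 for LGR5, -0.90 ± 0.21 for ASCL2 and 3.52 ± 0.20 for SLC26A3. Those of CA1 and ABCB1 were 3.00 ± 0.37 and 1.38 ± 0.10. All stayed past the test, but the setting makes arrays of models without signal nearly constant, which lowers the SE. Staying past the test therefore cannot decide whether these effects are shared by the 4 models. The absorptive colonocyte list had 21 of 27 members higher (22 adjusted over the list alone; adjusted p = 0.000281 with an estimated correlation) and the goblet and mucin list 9 higher and 1 lower of 22 (11 and 1 over the list alone; adjusted p = 0.0134 with an estimated correlation). Of 13 Wnt targets and feedback genes 8 fell (8 lower and 1 higher adjusted over the list alone; adjusted p = 0.0134 with an estimated correlation), and of 13 stem cell genes 5 fell (7 adjusted over the list alone; adjusted p = 0.0658 with an estimated correlation). The irinotecan handling list had 4 of 7 higher (4 adjusted over the list alone; adjusted p = 0.00151 with an estimated correlation) and the colorectal epithelium list 5 higher and 1 lower of 12 (7 and 1 over the list alone; adjusted p = 0.042 with an estimated correlation).

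Other lists in that average moved in part. The S phase list had 8 of 20 lower (9 adjusted over the list alone; adjusted p = 0.000419, and adjusted p = 0.399 with an estimated correlation). The G2 and M phase list had 0 of 20 past limma's test (0 adjusted over the list alone; adjusted p = 0.0497, and adjusted p = 0.667 with an estimated correlation), and the hypoxia and glycolysis list 7 of 15 lower (8 adjusted over the list alone; adjusted p = 0.00126, and adjusted p = 0.269 with an estimated correlation). In the remaining lists the camera test had adjusted p-values above 0.05: R-spondin and LGR axis 2 higher and 4 lower of 6, Paneth and crypt base secretory 1 higher and 2 lower of 6, p53 targets 2 higher and 3 lower of 21, interferon response 2 higher of 17, YAP and regenerative 2 higher of 10, and enteroendocrine 1 lower of 3 (INSM1, a neuroendocrine transcription factor). Among cell type lists, fibroblast and matrix had 1 higher and 1 lower of 9, endothelium 1 higher of 2 (ESAM), myeloid 2 higher of 3 (AIF1 and PTPRC), human B cell 1 lower of 5 (CD74), keratinised squamous epithelium 0 of 3, and skeletal muscle and fat 0 of 4. Adjusted over the list alone, the counts of these 12 lists differed for 3: 0 interferon response genes rose, 2 enteroendocrine genes fell and 1 gene of skeletal muscle and fat rose. The interferon response list ranked upward in its test while its median (-0.01) and mean (-0.02) were negative. In total 2672 genes changed, 1204 up and 1468 down, while 1492 rose and 1337 fell after quantile normalization once more. The mean of CR2513 and CR1560, the 2 models with equal durations, gave 77 genes, and the GAPDH covariate left 268 (188 up and 80 down); both were chosen after seeing the data.

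**Figure D2:**
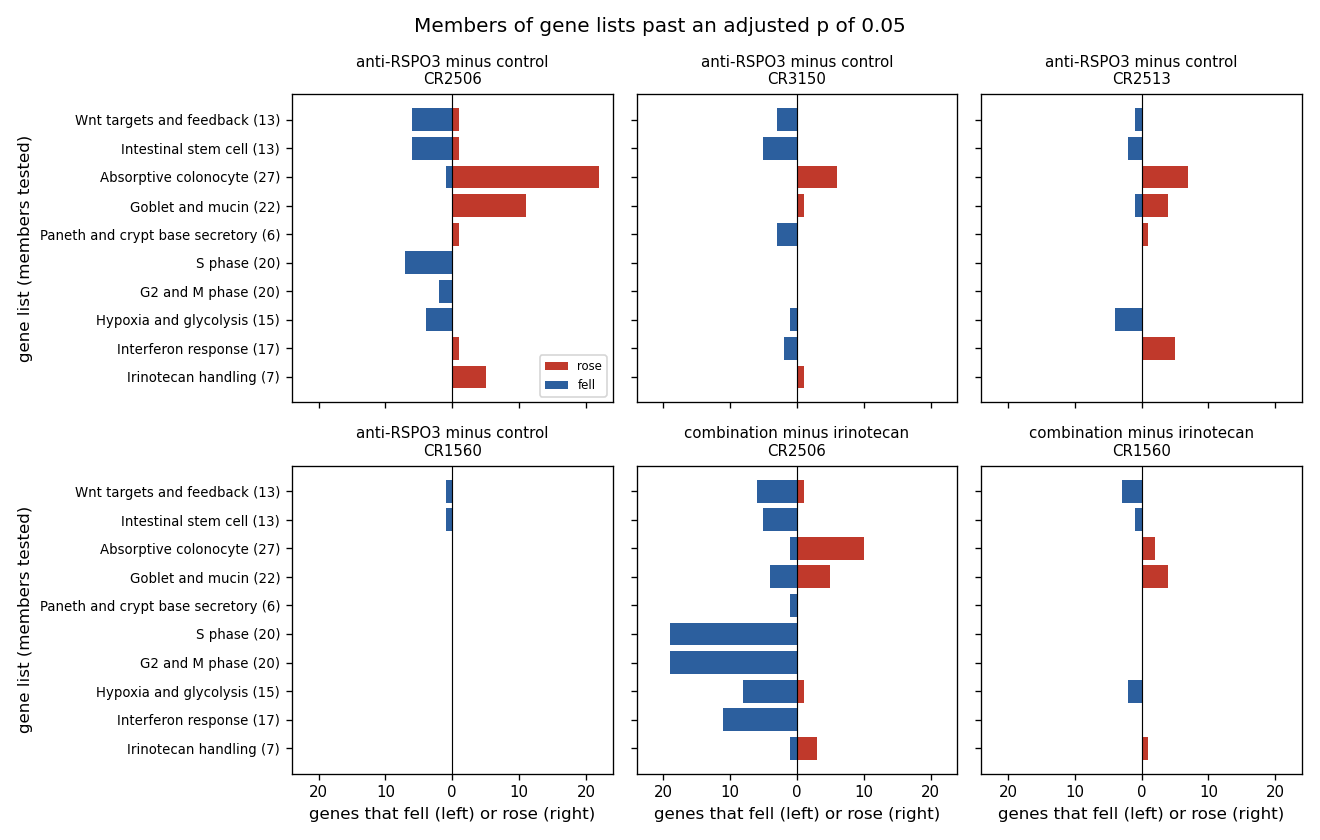
Number of members of 10 gene lists (vertical axis, members tested in brackets) that rose (red, to the right) or fell (blue, to the left) past an adjusted p of 0.05 in 6 comparisons (panels, n = 3 arrays per group). In CR2506 22 absorptive colonocyte genes rose with the antibody alone, and 19 S phase and 19 G2 and M phase genes fell when it was added to irinotecan.

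The same genes changed in more than 1 model more often than independent lists would give, though 1 spread per gene is shared by all models in the fit. In CR2506 and CR3150, 94 genes rose and 108 fell in both, where independent calls would give 19.1 and 39.7 (Fisher's exact test, adjusted p = 2.67e-41 and 1.58e-22 over 22 tests). CR2506 and CR2513 shared 168 rises and 58 falls against 27.5 and 13.99, and CR3150 and CR2513 shared 26 and 18 against 8.64 and 6.28. Fits of CR3150 and CR2513 alone called 1 gene each, too few to test an overlap. A test chosen after seeing the data took as many genes by the smallest p of each model's own fit: these pairs shared 84 and 82, 158 and 56, and 21 and 17. Calls of opposite direction numbered 11 and 1 in CR2506 and CR3150 against 32.9 and 23.0, 2 and 1 in CR2506 and CR2513 against 11.8 and 32.5, and 5 and 6 in CR3150 and CR2513 against 3.68 and 14.7. In CR2506, CR3150 and CR2513 together 22 genes rose, among them SLC26A3, KLF4, a transcription factor of differentiated epithelium, and the phosphatases DUSP4 and DUSP6 that restrain MAP kinases; 11 fell, among them LGR5, RGMB and PDK1, and 0 genes changed one way in all 4 models. KLF4, DUSP4, DUSP6 and PDK1 were chosen after their values were seen. The GAPDH difference was also higher in the treated arrays of these 3 models, by 0.235, 0.270 and 0.443, and CR2506 and CR3150 share longer treated durations. With that difference as a covariate, chosen after seeing the data, CR2506 and CR3150 shared 27 rises and 15 falls against 3.23 and 3.76 (Fisher's exact test, adjusted p = 1.42e-17 and 1.91e-05). CR2506 and CR2513 then shared 17 rises (adjusted p = 9.06e-15) and 2 falls (adjusted p = 0.0783), and CR3150 and CR2513 1 rise (adjusted p = 0.346) and 0 falls (adjusted p = 1). Across genes, which are not independent replicates, the log2 differences of CR2506 correlated with those of CR3150 (Pearson 0.415, Spearman 0.466), CR2513 (0.481, 0.464) and CR1560 (0.254, 0.281). The test of differing effects called 459 genes; LGR5 (adjusted p = 0.0119), RGMB (adjusted p = 0.00442), BMP4 (adjusted p = 0.0164), TNFRSF19 (adjusted p = 0.00153), EPHB3 (adjusted p = 0.0402), OLFM4 (adjusted p = 0.0328) and HOPX (adjusted p = 0.0464) were among them, as were 11 of 27 absorptive colonocyte genes and 6 of 17 interferon response genes. Restricted to genes detected in all 4 models, 168 were called, among them RGMB (adjusted p = 0.00796), BMP4 (adjusted p = 0.0256), 1 of 11 colonocyte and 4 of 16 interferon response genes. The other 5 genes were undetected in at least 1 model, so their test includes models without signal. Since treated and control durations differ in CR2506 and CR3150 alone, a differing effect also contains that difference in duration.

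Irinotecan alone, at 7 weeks against 4 for the controls, went with higher colonocyte and secretory transcripts in CR2506, where drug and duration cannot be told apart. REG1A rose 106-fold (log2 difference 6.73 ± 1.55 SE, n = 3 per group, adjusted p = 0.0117), SLC26A3 at least 16.6-fold (5.86 ± 0.49, adjusted p = 1.41e-08), CLCA4 at least 13.5-fold and CLCA1, a protein secreted with mucus, at least 23.1-fold. Of 27 absorptive colonocyte genes 12 rose (14 adjusted over the list alone; adjusted p = 0.000687 with an estimated correlation) and of 22 goblet and mucin genes 6 rose (14 adjusted over the list alone; adjusted p = 0.00091 with an estimated correlation). ABCB1 (at least 7.09-fold), ABCG2 (8.47-fold) and CES2 (2.06-fold) rose, 4 of 7 irinotecan handling genes (4 adjusted over the list alone; adjusted p = 0.000197 with an estimated correlation). In the Paneth and crypt base secretory list 2 of 6 rose (3 adjusted over the list alone; adjusted p = 0.0314 with an estimated correlation). LGR5 had a log2 difference of -1.11 ± 0.71 (adjusted p = 0.44) and AXIN2 of -0.72 ± 0.49 (adjusted p = 0.479). The p53 targets, which DNA damage commonly raises, had 0 of 21 past the test in limma (0 adjusted over the list alone), with GDF15 at 0.75 ± 0.30 (adjusted p = 0.159). In total 513 genes changed, 339 up and 174 down. The 3 prime minus 5 prime differences were 0.449 ± 0.0239 SD against 0.273 ± 0.0268 SD for GAPDH and 2.50 ± 0.252 SD against 2.02 ± 0.0831 SD for ACTB (n = 3, exact permutation p = 0.1 each). The count was 249 and 201 without control replicates 1 and 3, 312 and 184 without irinotecan replicates 1 and 3, and 84 in a fit of this model alone. Without irinotecan replicate 3 the colonocyte, goblet and Paneth counts were 7, 3 and 0, and without control replicate 3 the goblet count was 3. The call of REG1A ended without irinotecan replicate 3 (6.02) or control replicate 1 (5.22). The Paneth count was also 0 without control replicate 1, and 1 without control replicate 2 or 3.

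In CR1560 irinotecan changed 79 genes, 39 up and 40 down, at equal durations. ASAP3, a regulator of ARF GTPases, rose at least 2.76-fold (log2 difference 2.48 ± 0.42 SE, n = 3 per group, adjusted p = 0.00157), and ATP10B, a lipid flippase, 4.58-fold. DHRS2, a mitochondrial reductase, fell at least 4.18-fold (-3.07 ± 0.57, adjusted p = 0.00403), the NADPH oxidase NOX5 6.02-fold and the calcium channel TRPV6 4.24-fold. RSPO3 fell 1.90-fold (-0.93 ± 0.15, adjusted p = 0.00112). Of 27 absorptive colonocyte genes 0 rose and 1 fell (HPGD, a prostaglandin dehydrogenase, 2.29-fold), and 0 of 13 Wnt targets and feedback and 0 of 21 p53 target genes passed limma's test, with 1086 genes at an unadjusted p under 0.05 overall. The call of HPGD ended without control replicate 2 (-1.18) or 3 (-0.88) or any 1 irinotecan array (-1.05 to -1.32), and that of ATP10B without control replicate 3 (1.49) or irinotecan replicate 2 (1.80) or 3 (2.06). Counts were 162 and 44 without control replicates 1 and 2 and 47 without irinotecan replicate 2. A fit of this model alone called 65, of which 17 were among the 79, and 2 of the 7 named genes past the test passed in it. The 3 prime minus 5 prime differences were 0.414 ± 0.0318 SD against 0.238 ± 0.0783 SD for GAPDH and 1.79 ± 0.0134 SD against 1.504 ± 0.0545 SD for ACTB (n = 3, exact permutation p = 0.1 each).

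Adding the antibody to irinotecan in CR2506, with equal durations of 7 weeks, went with lower cell cycle transcripts and with a larger GAPDH difference. Within these arrays, whether the antibody or RNA quality lowers the transcripts was not settled. In the S phase list 19 of 20 genes fell (19 adjusted over the list alone; median log2 difference -1.74; adjusted p = 2.98e-07, and adjusted p = 0.409 with an estimated correlation), such as the licensing factor CDT1 (8.91-fold), DTL (6.97-fold) and the helicase subunit MCM5 (6.57-fold). In the G2 and M phase list 19 of 20 fell (20 adjusted over the list alone; median -1.90; adjusted p = 3.77e-05, and adjusted p = 0.452 with an estimated correlation), including BUB1B (6.91-fold), CENPE (6.85-fold) and MKI67 (5.42-fold). LGR5 fell at least 5.27-fold (-3.32 ± 0.71 SE, n = 3 per group, adjusted p = 0.000672), LRIG1 5.31-fold, CDCA7 4.75-fold, RGMB 2.45-fold and ZNRF3 2.31-fold, while the Wnt inhibitor DKK1 rose 5.02-fold. The intestinal stem cell list had 5 of 13 lower (5 adjusted over the list alone; adjusted p = 0.528) and the Wnt targets and feedback list 6 lower and 1 higher of 13 (8 and 1 over the list alone; adjusted p = 0.212). FRZB, a secreted Wnt antagonist, fell at least 11.2-fold, the lipid transporter ABCA12 42.2-fold, CLCA1 at least 23.1-fold and the chemokine receptor CCR6 23.7-fold. CLCA1 had a mean of 3.58 in the combination, 8.53 with irinotecan and 3.28 in controls, so its fall ends near the control level. Without combination replicate 3 the calls of CDCA7 (-1.02), LRIG1 (-1.66) and ZNRF3 (-0.54) ended and 3 stem cell genes fell. That of ZNRF3 also ended without irinotecan replicate 1 (-0.995) or 2 (-1.21) or combination replicate 2 (-1.23).

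Colonocyte genes moved both ways in that comparison. Of 27 absorptive colonocyte genes 10 rose and 1 fell (11 and 2 over the list alone; adjusted p = 5.37e-06, and adjusted p = 0.081 with an estimated correlation): CLCA4 rose 8.84-fold, CA2 7.12-fold and LYPD8 6.66-fold, and CA4 fell 10.1-fold. In the goblet and mucin list 5 rose and 4 fell of 22 (5 and 4 over the list alone; adjusted p = 0.138), MUC12 up 5.57-fold and ZG16 down at least 3.84-fold. That list ranked upward with a median of 0.12 and a mean of -0.46. ABCB1 rose 21.7-fold beyond irinotecan alone (4.44 ± 0.22, adjusted p = 4.36e-14), ABCG2 2.59-fold, and TDP1, which repairs topoisomerase I lesions, fell 2.94-fold, with 3 of 7 irinotecan handling genes higher and 1 lower (4 and 1 over the list alone; adjusted p = 0.0435 with an estimated correlation). ABCB1 was detected in 1 model, so its SE may be too small beside SDs of 0.525 (combination) and 0.626 (irinotecan). FIGN rose at least 6.58-fold, PTPRD at least 6.17-fold, the cholesterol transporter ABCA1 at least 4.78-fold and PDK4, a brake on glucose oxidation, 11.7-fold. Of 17 interferon response genes 11 fell (12 adjusted over the list alone; adjusted p = 0.0648), IFI44L by 5.59-fold and IFIT3 by 3.93-fold. In the fibroblast and matrix list 3 rose and 1 fell of 9 (3 and 1 over the list alone; adjusted p = 0.0648), COL3A1 up 2.56-fold and COL1A1 2.08-fold. Both endothelial genes rose (2 over the list alone; adjusted p = 0.057), ESAM by 2.54-fold, with 1 past the test without any 1 of the 6 arrays. Of 3 myeloid genes PTPRC (2.57-fold) and AIF1 (2.55-fold) rose and 1 fell (2 and 1 over the list alone; adjusted p = 0.212). The interferon count was 5 and 4 without combination replicates 1 and 2, where the calls of IFIT3 (-1.48 and -1.32) and IFI44L (-1.80 and -1.38) ended, the latter also without irinotecan replicate 3 (-2.26). Calls also ended for ABCG2 (0.95 without combination replicate 1), for AIF1 (1.05), COL1A1 (0.61) and TDP1 (-0.69) without combination replicate 3, for COL1A1 (0.90) without irinotecan replicate 1 and TDP1 (-1.38) without irinotecan replicate 2, and for ESAM (1.09 to 1.42) without any 1 irinotecan array or combination replicate 1 or 2. The goblet count of rises was 3 without irinotecan replicate 2 or combination replicate 2.

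In all 4708 genes changed in that comparison, 1038 up and 3670 down, and the median of all genes was -0.19. In a fit of this model alone 3063 changed. After quantile normalization once more the median was -0.02 and 42.8% of 4143 calls rose, against 22.0%. The combination arrays had a GAPDH 3 prime minus 5 prime difference of 0.930 ± 0.251 SD against 0.449 ± 0.0239 SD with irinotecan (n = 3, exact permutation p = 0.1), with 1.14 and 0.994 on replicates 2 and 3 and 0.653 on replicate 1. With that difference as a covariate 1486 genes changed, 13 S phase genes among them, and with replicates 2 and 3 dropped 756 genes, 3 S phase and 1 G2 and M phase gene; both settings were chosen after seeing the data. The S phase and G2 and M phase medians on replicate 1 alone were -0.85 and -0.26, and without replicate 3, whose MKI67 intensity was 6.43 beside 9.98 and 9.86 on the other arrays of its group, 10 G2 and M phase genes fell. TDP1 and ZNRF3 had differences of 0.14 and 0.07 with replicates 2 and 3 dropped.

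**Figure D3:**
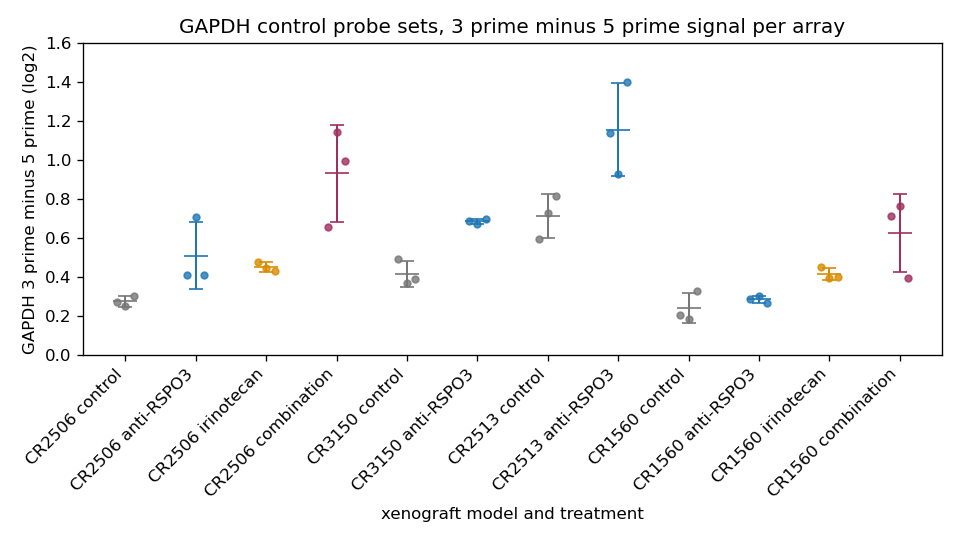
Log2 difference between the 3 prime and 5 prime GAPDH control probe sets (vertical axis) per array for the 12 groups (horizontal axis); points are arrays, horizontal marks means, bars 1 SD (n = 3). The highest CR2506 values, 1.14 and 0.994, belong to replicates 2 and 3 of the combination group.

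Adding the antibody to irinotecan in CR1560 lowered Wnt target transcripts. AXIN2 fell 20.9-fold (log2 difference -4.39 ± 0.49 SE, n = 3 per group, adjusted p = 1.53e-06), TNFRSF19 7.99-fold (-3.00 ± 0.26, adjusted p = 1.78e-08) and BMP4 2.06-fold, so 3 of 13 Wnt targets and feedback genes fell (5 adjusted over the list alone; adjusted p = 1.73e-05, and adjusted p = 0.0092 with an estimated correlation). SLC2A3, a glucose transporter, fell at least 45.1-fold, ELF5, an epithelial transcription factor, 26.4-fold, HLA-DPA1 14.9-fold and HOPX 2.77-fold. REG4, a secretory cell lectin, rose 7.82-fold and ST6GALNAC1, a mucin sialyltransferase, 2.52-fold, with 4 of 22 goblet and mucin genes higher (6 higher and 1 lower adjusted over the list alone; adjusted p = 6.3e-05, and adjusted p = 0.0708 with an estimated correlation). PRKACB, a catalytic subunit of protein kinase A, rose 12.8-fold, MITF 12.3-fold, STOM 10.3-fold, ATP2A3 8.71-fold, TRPV6 9.15-fold and RSPO3 2.07-fold. TRPV6 and RSPO3 had fallen with irinotecan alone on the same irinotecan arrays, so their rises start from a lowered level. None of 20 S phase genes passed limma's test (0 adjusted over the list alone). In total 308 genes changed, 146 up and 162 down; a fit of this model alone called 417, 178 of them among the 308. Counts were 163 and 195 without irinotecan replicates 2 and 3, 114 and 132 without combination replicates 1 and 2, and 167 with the GAPDH covariate, that difference being 0.623 ± 0.200 SD against 0.414 ± 0.0318 SD (n = 3, exact permutation p = 0.3). The call of BMP4 ended without irinotecan replicate 3 (-0.93) or combination replicate 1 (-0.86) or 2 (-0.91), and that of HOPX without irinotecan replicate 2 (-0.88) or combination replicate 1 (-0.98) or 2 (-1.40), and the goblet count was 2 without irinotecan replicate 3 or combination replicate 1 or 2.

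The effect of the antibody on top of irinotecan overlapped its effect alone within a model, in comparisons that share no array. In CR2506 315 genes rose and 751 fell in both, against 74.1 and 327 for independent calls. Fisher's exact test gave adjusted p = 4.93e-130 and 7.88e-185, over genes that are not independent replicates. The differences correlated across genes (Pearson 0.600, Spearman 0.631). Sharing no array does not part the antibody from RNA quality there, since the GAPDH difference was larger in both treated groups, by 0.235 and 0.481. The comparison of the antibody alone also contains a longer treated duration. Whether this overlap holds with the GAPDH difference as a covariate was not tested, so a shared effect of RNA quality stays open. In CR1560 all 7 genes that fell with the antibody alone also fell in the combination, against 0.0994 (adjusted p = 2.8e-13), and the correlation was 0.454 (Spearman 0.422). Between models, combination minus irinotecan shared 24 rises against 9.43 (adjusted p = 3.23e-05) and 18 falls against 26.1 (adjusted p = 0.0916). Irinotecan minus control shared 1 rise and 0 falls between CR2506 and CR1560, against 0.330 and 0.336.

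Against controls, the combination changed 5256 genes in CR2506 (1454 up and 3802 down, 27.7% rises; 47.1% after quantile normalization once more), at 7 against 4 weeks, and 421 in CR1560 (216 up and 205 down). In CR2506 ABCB1 rose at least 154-fold (log2 difference 8.94 ± 0.22 SE, n = 3 per group), CLCA4 at least 119-fold and CA2 at least 130-fold. There LGR5 fell at least 11.4-fold, AXIN2 3.21-fold, and the chemokines PPBP and CXCL6 22.0-fold and 20.2-fold. Of 27 absorptive colonocyte genes 19 rose and 1 fell (19 and 1 over the list alone; adjusted p = 0.000934 with an estimated correlation), and of 20 S phase genes 19 fell (19 adjusted over the list alone; adjusted p = 0.317 with an estimated correlation). In CR1560 AXIN2 fell 25.0-fold (-4.64 ± 0.49, adjusted p = 9.3e-07), TNFRSF19 6.35-fold and ELF5 18.9-fold, while PRKACB rose at least 14.9-fold and MITF 14.9-fold; the Wnt targets and feedback list had 3 of 13 lower (3 adjusted over the list alone; adjusted p = 0.0338 with an estimated correlation). The medians of all genes were -0.18 in CR2506 and 0 in CR1560. Dropping replicates 2 and 3 of the CR2506 combination left 1196 genes, and the GAPDH covariate 702, with AXIN2 at 0.15. In CR1560 counts were 170 and 150 without control replicates 1 and 2, 105, 105 and 876 without combination replicates 1, 2 and 3, 32 with the GAPDH covariate and 1296 in a fit of this model alone, 328 of them among the 421. The GAPDH difference was 0.930 ± 0.251 SD against 0.273 ± 0.0268 SD in CR2506 and 0.623 ± 0.200 SD against 0.238 ± 0.0783 SD in CR1560 (n = 3, exact permutation p = 0.1 each).

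The interaction tests whether the antibody effect differed with irinotecan present. In CR2506 the controls alone have 4 weeks, so it also contains the difference in duration, and a rise with time alone would make it negative. In CR2506 SLC26A3 (-6.41 ± 0.70 SE, adjusted p = 4.22e-06), CA4 (-5.76 ± 0.68), CLCA1 (-5.97 ± 1.51), MUC5B (-3.65 ± 0.92) and ABCB1 (-2.76 ± 0.31) had a smaller rise or a fall from the antibody on top of irinotecan. Control means of SLC26A3, CLCA1, MUC5B and ABCB1 lie below the limit of 4, so these sizes are not exact. Values below 4 were also set to 4, a setting chosen after seeing the data. The interactions were then -4.60 for SLC26A3, -5.10 for CLCA1, -2.98 for MUC5B and -1.09 for ABCB1. All stayed past the test, but the setting also lowers the spread in models without signal, so passing it adds little. Of 27 absorptive colonocyte genes 10 had a negative interaction past the test (15 adjusted over the list alone; adjusted p = 0.0487 with an estimated correlation), and 4 of 22 goblet and mucin genes (10 adjusted over the list alone; adjusted p = 0.0487 with an estimated correlation). The call of CLCA1 ended without control replicate 1 (-5.70), anti-RSPO3 replicate 3 (-5.45), irinotecan replicate 3 (-5.68) or combination replicate 3 (-5.61), and that of MUC5B without control replicate 3 (-3.03), anti-RSPO3 replicate 1 (-2.90), irinotecan replicate 3 (-3.05) or combination replicate 2 (-3.42). In all 505 genes passed in CR2506, 110 positive and 395 negative (21.8% positive; 49.7% of 330 calls after quantile normalization once more), and the median of all genes was -0.16. Counts were 268 and 238 without control replicates 1 and 3, 241 without irinotecan replicate 3, 2029 and 265 without combination replicates 1 and 2, and 48 in a fit of this model alone. In CR1560 6 genes passed, all negative (SERPINA5, EVA1A, MATN3, MYLK, GJB6 and MAPT, named after their values were seen). With the replicate number as a block 2 passed, 1 positive and 1 negative, of which SERPINA5 was among the 6. None of the 6 stayed past the test with each array left out in turn, and simulated data with no effect gave 4 calls on average. AXIN2 had an interaction of -2.74 ± 0.70 (adjusted p = 0.213), and -3.58 without combination replicate 3, where it passed (adjusted p = 0.00155). The count was 0 without control replicate 3, anti-RSPO3 replicate 1 or combination replicate 2, 1 without irinotecan replicate 2 or combination replicate 1, 2 without control replicate 2, and 35, 40 and 65 without control replicate 1, anti-RSPO3 replicate 3 and combination replicate 3. Limma called 422 genes there at an unadjusted p under 0.05.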

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

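The tests chosen only after the result was seen were those of an array-wide offset, of mouse RNA, of duration in CR3150 and of LGR5 on 1 array of CR3150, the genes detected in all 4 models, the CR1560 splits by pairs, and the fits with the GAPDH difference as a covariate.

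The test of differing antibody effects between the 4 models called 459 genes. Treated and control durations are unequal in CR2506 and CR3150 and equal in CR2513 and CR1560. A differing effect therefore also contains the differing durations, and the 2 cannot be told apart. The stem cell and Wnt genes among them were LGR5 (adjusted p = 0.0119), TNFRSF19 (adjusted p = 0.00153), BMP4 (adjusted p = 0.0164), OLFM4 (adjusted p = 0.0328), EPHB3 (adjusted p = 0.0402), RGMB (adjusted p = 0.00442) and HOPX (adjusted p = 0.0464). RGMB (adjusted p = 0.00796) and BMP4 (adjusted p = 0.0256) were also among the 168 called on genes detected in all 4 models, and the other 5 were undetected in at least 1 model, so their test includes models without signal. LGR5 had log2 differences of -4.98 in CR2506, -4.16 in CR3150 and -2.66 in CR2513, and lay at the floor in CR1560. TNFRSF19 had -1.92 in CR1560. The interaction of antibody and irinotecan called 505 genes in CR2506, where it also contains the shorter duration of the controls. It called 6 in CR1560, and 2 with the replicate number as a block.

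Counts were also taken over other splits of the same arrays. A comparison of 3 with 3 arrays has 10 splits, too few for a share under 0.05. The real split of the antibody and control arrays gave 1854 genes in CR2506, 839 in CR3150 and 560 in CR2513, and the highest of the others 7, 258 and 35, so 1 of the 10 splits gave as many in each. In CR1560 4 of the 10 splits gave as many as the real 9, the highest other 73, which may come from a structure of the samples. The real split parts all 3 pairs of same-numbered arrays there, though whether these arrays are paired is not settled. The other 3 splits that do so gave 2, 1 and 0 genes, and the 6 splits that keep 2 pairs together gave between 0 and 73. For irinotecan minus control 1 of the 10 splits gave as many in CR2506 (513, highest other 10) and 1 in CR1560 (79, highest other 52). For combination minus irinotecan it was 1 in CR2506 (4708, highest other 2116) and 1 in CR1560 (308, highest other 19), and for combination minus control 1 in CR2506 (5256, highest other 1872) and 1 in CR1560 (421, highest other 128). Among 100 splits, chance was excluded for the mean of 4 models (1 split as large, 2672 genes, highest other 1135). The total of 62 list shifts was also the largest (1 split, highest other 50). That excludes chance for no single list, since another split gave 50 shifts at the preset correlation. With an estimated correlation 26 of the 62 held. For the 459 genes of differing effects 3 splits gave as many, counting the real one, and the highest other gave 1623. Such splits can carry real antibody effects into the differences between models, so they cannot decide on chance there. For the interaction chance was not excluded in CR2506 (7 splits; 505 genes, highest other 2914) or CR1560 (27 splits; 6 genes, highest other 162). Splits with several times the real count can come from a structure of the samples, or from treatment effects that a split carries into these contrasts, and which of them was not tested.

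The combination group of CR2506 had the broad fall of cell cycle genes against irinotecan alone. A larger share of mouse RNA would lower all tumour transcripts alike, but the S phase median lay -1.54 from that of the colorectal epithelium list (-1.74 against -0.20), which argues against it as the whole cause. An array-wide offset is argued against for the calls, since 72.1% of called genes were called in the same direction after quantile normalization once more, but the excess of falls stays open, since 42.8% of calls then rose and that step centres the arrays. Loss of signal towards the 5 prime end cannot be told apart from the treatment: across called genes its predicted and observed differences correlated at 0.173, but the median was -0.02 predicted (SD 0.319) against -0.67 observed, and with the covariate 1347 of the calls were shared while the median size went from 0.789 to 0.600 and the median SE from 0.204 to 0.263. Antibody alone against irinotecan in CR2506, both at 7 weeks, had 12 of 20 S phase genes lower (median -1.04) and 0 higher. The G2 and M phase list there had 12 of 20 lower (median -1.60) and 0 higher. GAPDH differences were 0.508 ± 0.173 SD and 0.449 ± 0.0239 SD, so that lower level came with little difference in this measure. It does not decide for the combination arrays. The antibody given with irinotecan may lower these cell cycle genes, and RNA quality may add to it.

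The colonocyte genes rose with the antibody in CR2506 and CR3150, where the treated groups also have longer durations. In CR2506 the antibody and irinotecan groups both have 7 weeks, and there 9 of 27 absorptive colonocyte genes were higher with the antibody and 1 lower, which argues against duration as the whole cause. In that comparison 1433 genes changed. LGR5 differed by -3.87 ± 0.71 (adjusted p = 0.00132), ASCL2 by -2.43 ± 0.58 (adjusted p = 0.00883) and SLC26A3 by 1.99 ± 0.49 (adjusted p = 0.0108). KRT20 of the colonocyte list, named after its value was seen, differed by 0.40 ± 0.11 (adjusted p = 0.0199). AXIN2 (-1.27 ± 0.49, adjusted p = 0.0886), CA1 (1.84 ± 0.77, adjusted p = 0.114) and CLCA4 (0.99 ± 0.51, adjusted p = 0.203) did not pass. Of 13 Wnt targets and feedback genes 6 were lower and 0 higher, and of 13 stem cell genes 5 were lower and 0 higher. In CR3150 the rise of 6 genes, like the falls of LGR5, REG1A and DEFA6, cannot be told apart from a longer duration, since no comparison in that model has equal durations, and neither can the 12 rises with irinotecan in CR2506. The antibody may raise these genes, and the choice of irinotecan as reference leaves an effect of irinotecan open.

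The calls of CR3150 and CR2513 rest on a spread shared over the models, since fits of each model alone called 1 gene in each. In simulated data with no effect the mean number of false calls was 100.8 for CR3150, and with 200 genes changed 199 of its 384 calls were false, so false calls from that shared spread may account for part of its 839 genes. It was 8.95 for CR2513, which argues against independent false calls of this kind as the source of most of its 560 genes. With 200 genes changed in simulated data, 37 of its 215 calls were false. The simulated deviations were drawn independently for each gene, so deviations that genes share, such as those from RNA quality, were not covered. With the GAPDH difference as a covariate 52 genes changed in CR2513. Replicate 2 of the CR3150 antibody group stood apart from its group, but the nearest other model was 2.07 times as far from it as CR3150 was, and its LGR5 value lay 2.89 below the lowest control, which argue against tissue of another model and against an untreated tumour. The treatment, named by the design, stays open for the rest.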

How the results depend on the processing

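The tests chosen after the data were seen were the fit of each model alone over its detected genes, the GAPDH covariate, dropping arrays 2 and 3 of the CR2506 combination, the mean of 2 models and the genes detected in all 4. No trend and the mean of all probe sets moved none of the 15 counts by over 1.5 times. Of the gene results 174 kept direction and side of the threshold after quantile normalization once more while 9 fell short and 1 newly passed, and of 62 list shifts 60 did. With the GAPDH covariate 130 gene results kept direction and side, 53 fell short and 1 reversed, with only the arrays of the same model 87 did and 86 fell short, and over its detected genes 102 did and 67 fell short. Of the 62 list shifts 9 fell short with the GAPDH covariate, 6 in each of these fits of a model alone and 36 with an estimated correlation.

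With only the arrays of the same model, the antibody changed 627, 3, 0 and 0 genes in CR2506, CR3150, CR2513 and CR1560 in limma. Irinotecan changed 96 in CR2506, combination minus irinotecan 2781 in CR2506 and 200 in CR1560, combination minus control 3470 and 912, and the interaction called 44 and 1. Over the genes detected in the model, the antibody changed 682, 1, 1 and 0 in limma, irinotecan 84 in CR2506, combination minus irinotecan 3063 in CR2506 and combination minus control 1296 in CR1560, and the interaction called 48 and 0. The cause was not tested. In simulated data such fits recovered 56% of genes changed 2-fold and 91% of those changed 4-fold in CR3150, and 79% and 100% in CR2513.

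Array weights gave 3724, 4947, 2689 and 54 for the antibody. They gave 1603 and 705 for irinotecan in CR2506 and CR1560, 2155 for combination minus irinotecan and 3269 for combination minus control in CR1560, 2530 and 218 for the interaction, 5634 for the mean of 4 models and 4680 for genes whose anti-RSPO3 effect differs between 4 models. The cause was not tested.

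With the GAPDH covariate the antibody changed 926, 260 and 52 genes in CR2506, CR3150 and CR2513. Combination minus irinotecan changed 1486 and 167 in CR2506 and CR1560, combination minus control 702 and 32, irinotecan 50 in CR1560, the interaction in CR1560 1 and the mean of 4 models 268. AXIN2 in combination minus control of CR2506 turned to 0.15 (adjusted p = 0.939). Without arrays 2 and 3 of the CR2506 combination, counts were 756 against irinotecan, 1196 against control and 250 for the interaction, and TDP1 and ZNRF3 against irinotecan turned to 0.14 (adjusted p = 0.953) and 0.0742 (adjusted p = 1). That group then has 1 array, assumed to vary like the others.

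In CR1560 no filter on dim probe sets gave 17 genes for the antibody and 15 for the interaction, and the stricter filter 5 and 1, and 49 for irinotecan. Quantile normalization once more gave 330 and 0 for the interaction in CR2506 and CR1560 in limma, and the replicate number as a block 2 in CR1560. Same-numbered arrays correlated over 0.1 in 18 of 42 pairs, between -0.32 and 0.63 with a median of 0.049. In CR1560 all pairs of anti-RSPO3 arrays with control and combination arrays did so. Control replicate 2 nevertheless correlated best with anti-RSPO3 replicate 3 (0.261). The control and combination arrays of CR1560 correlated at 0.169, -0.125 and 0.224, so whether the numbers pair its arrays is not settled. For the antibody there the block called 10 genes, 8 of them among the 9, and changed no named call or list shift. The block moved no other count by over 1.5 times. The mean of the 2 models with equal durations gave 77, differing effects on genes detected in all 4 models 168, and an estimated correlation left 26 of 62 list shifts. The cause was not tested for these.

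Leaving out each array in turn gave 1152 to 1487 genes for the antibody in CR2506, 348 to 1640 in CR3150, 106 to 934 in CR2513 and 7 to 37 in CR1560. It gave 184 to 471 and 44 to 162 for irinotecan in CR2506 and CR1560, 3279 to 5510 and 114 to 380 for combination minus irinotecan, 3926 to 5976 and 105 to 876 for combination minus control, 238 to 2029 and 0 to 65 for the interaction in limma, and 2139 to 3798 for the mean of 4 models. Of the gene results under these omissions 1189 kept direction and side of the threshold, 183 fell short of it and 2 newly passed it. Between 38.2% and 40.6% of probe sets at the floor limit what the arrays resolve.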

Other observations

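The gene named after its values were seen in the first paragraph is SERPINE2, and the tests of the equal-duration groups of CR1560 were also chosen after the data were seen.

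Beyond the comparisons given above, some hypoxia and glycolysis genes fell in the next 3, where the list's shift did not hold with an estimated correlation. They also fell in combination minus irinotecan of CR2506, where 5 to 9 of 15 were lower and 0 to 1 higher with each array left out in turn. In combination minus control of CR2506, 12 of 15 fell (12 adjusted over the list alone; adjusted p = 0.00076, and adjusted p = 0.31 with an estimated correlation). In irinotecan minus control of CR2506, 2 of 15 fell (4 adjusted over the list alone; adjusted p = 2.33e-05, and adjusted p = 0.238 with an estimated correlation), with 1 without irinotecan replicate 3. In combination minus irinotecan of CR1560, 2 of 15 fell (2 adjusted over the list alone; adjusted p = 4.18e-05, and adjusted p = 0.252 with an estimated correlation), and limma called 0 of them without any 1 irinotecan array or without combination replicate 1 or 2. SERPINE2, an inhibitor of serine proteases, had the smallest p of the test of differing antibody effects (adjusted p = 1.16e-08), with log2 differences of 1.90 in CR2506, 0.19 in CR3150, 0.77 in CR2513 and -0.12 in CR1560. Unequal durations in CR2506 and CR3150 enter that test too.

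Secretory and cell cycle genes also moved in combination minus control of CR2506. In the goblet and mucin list 10 of 22 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 0.0125 with an estimated correlation). Of 7 irinotecan handling genes 4 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.000653 with an estimated correlation). In the G2 and M phase list 14 of 20 fell (14 adjusted over the list alone; adjusted p = 0.0241, and adjusted p = 0.697 with an estimated correlation), with 6 without control replicate 3 and 2 without combination replicate 3. Between the models, combination minus control shared 67 rises against 20.6 for independent calls (Fisher's exact test, adjusted p = 2.34e-19) and 63 falls against 44.9 (adjusted p = 0.00194). In CR1560 the antibody and irinotecan groups, both at 6 weeks, differed in 272 genes, 124 higher and 148 lower with the antibody.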
